A study of Homo sapiens with 9 samples.

How the data were processed

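RNA from PANC-1, an established human cell line derived from a ductal carcinoma of the pancreas, was hybridised to 9 one-colour Agilent arrays, 1 per sample. Per the labels, 3 samples were untreated controls, 3 received 500 nM Ika and 3 received 1.5 µM Ika, all at 24 hr, and the RNA was amplified and labelled with Cy3 in a low-input whole-transcriptome protocol. Ika stands for ikarugamycin, as the series title gives it. Per the file headers, the scanner software (Agilent Feature Extraction, version 10.7.1.1 in the headers and 10.7.3.1 in the submitters' processing notes) subtracted the background and removed spatial trends within each array, and the deposited processed intensity of each spot is on a linear scale with no scaling between arrays. The deposited spot mean intensity and local background intensity are raw brightness values, per the file headers. The authors' series table holds log2 values: its column medians were 4.34 in all 9 columns, each column correlated best with the log2 processed intensity of its own array, and its quartiles were equal between columns, so its scale (log2) and its centring (by quantiles) could be read from the values, while the software that made it is not given in the sources used here. The direction is that of brightness, since no ratio is involved.

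Each array held 62976 spots, of which 4259 were controls and were left out. The remaining 58717 spots belonged to 50599 probes. Spots with outlier flags were left out, the log2 processed intensities of the spots of a probe were averaged, and each array's 75th percentile was subtracted. No spot outside the controls was saturated. A probe was kept if it was well above background on every array of at least 1 group, which left 27211 probes. Gene names come from the files and were updated through RefSeq tables of the assembly GRCh38, which were used for names only: 28353 probes were named by accession, 2492 carried a current symbol, 593 an older symbol, and 19161 kept the name in the file. Where several kept probes had 1 gene name, the probe with the highest mean over all 9 arrays represented the gene, which gave 20298 genes. Of these, 5024 had several kept probes, and 80.5% of the other probes of called genes changed in the same direction as the chosen probe. Probe positions are given as in the files, in the build hg19 named in the file headers; no gene annotation of that build was used, so exon or untranslated region is not stated. The probe for COX1 has a position on a nuclear chromosome in the files, where a copy of the mitochondrial sequence lies.

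Groups were compared with limma (version 3.58.1, R 4.3.3): lmFit and eBayes on all 9 arrays in 1 fit with 6 residual degrees of freedom, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The number called that also changed at least 2-fold is given beside it. Where a gene was well above background on every array of 1 group and on none of another, the fold is a bound: the bright group's mean against the dim group's mean, where each dim array took the higher of its lowest signal well above background and the probe's own signal. The labels do not say whether samples came from separate cultures, so that p-values measure only the spread between these arrays, which may be technical.

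A total of 36 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. The lists were glycolysis, pentose phosphate pathway, TCA cycle, oxidative phosphorylation, hypoxia, cholesterol synthesis, fatty acid synthesis, LXR targets, clathrin-mediated endocytosis, lysosome, autophagy, unfolded protein response, integrated stress response, heat shock, NRF2 targets, iron, metallothioneins, p53 targets, DNA replication, mitosis, replication-dependent histones, apoptosis, immediate early genes, NF-kB targets, interferon response, TGF-beta and mesenchymal genes, epithelial genes, MYC targets, ribosomal proteins, nucleotide synthesis, amino acid metabolism, mucins and glycan synthesis, markers of acinar and endocrine, of immune and blood, and of stromal and endothelial cells, and mitochondrial transcripts, the last set as a sign of RNA quality. The groups, tests, lists and alternatives were set before the data were examined. So was the rule for named genes: the 8 largest rises and falls per dose among genes with a current symbol that is not a placeholder (such as LOC or open reading frame names), well above background on all arrays compared and with no overlap between groups, the 3 largest bounds per direction, all glycolysis genes, the 4 members of every other list with the smallest p, and the 5 largest rises and falls between doses.

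Slide and scan date split the arrays in the same way. Slide 1 held the 3 controls and 500 nM replicate 1, and slide 2 held 500 nM replicates 2 and 3 and the 3 arrays of 1.5 µM. With slide as a block, the change at 500 nM equals that of replicate 1 against the controls and the change from 500 nM to 1.5 µM equals that within slide 2; no slide held both controls and 1.5 µM. Alternatives covered normexp background correction with an offset of 50, quantile scaling, centring on the median or on E1A spike-in probes, filters on dim probes, outlier flags, the mean of a gene's probes, the groups in the fit, blocks by replicate number, slide and scan date, another model of the spread, the authors' log2 values, and leaving out each array. Fits within each slide were added after the data were seen.

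Data were simulated from these arrays' means and spreads over 20285 genes, with 50 genes changed at each fold. The fit for 500 nM against control recovered 8 of 50 at 1.25-fold, 21 at 1.5-fold, 39 at 2-fold and 48 at 4-fold. It made 6 false calls among 122. For 1.5 µM against control the fit recovered 8, 30, 36 and 46, with 10 false calls among 130. For 1.5 µM against 500 nM it recovered 5, 26, 40 and 48, with 8 false calls among 127. Only 200 genes were changed each time and no slide difference was drawn, so these rates need not hold for the real arrays. A list shifted by 0.3 log2 in the 500 nM comparison was called in 20 of 20 draws, with 0 false calls of the other lists at adjusted p under 0.05. Genes were drawn independently there, whereas the estimated correlation in the data was 0.422 for DNA replication. These draws therefore do not test list calls where genes vary together. The number of arrays limits the precision: 3 per group. Figures were drawn with matplotlib 3.10.9.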

Results

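The transcripts of PANC-1 cells were measured after 24 hr with 500 nM or 1.5 µM ikarugamycin (Ika), a macrolactam made by Streptomyces and known as an inhibitor of clathrin-mediated endocytosis, and in untreated cells. The series title names glycolysis in pancreatic cancer as its subject. Each of the 3 groups had 3 arrays, and 52.3% to 56.0% of the 50599 probes were well above background on an array. The 75th percentile of the processed intensity lay between 269 (500 nM replicate 1) and 429 (500 nM replicate 3) on the linear scale. Replicates correlated across genes at r = 0.997 in every pair of controls, 0.9897 to 0.997 at 500 nM and 0.996 to 0.997 at 1.5 µM. All changes below are log2 fold changes with the standard error from limma, with 3 arrays in each group, relative to each array's 75th percentile, and a gene is said to rise or fall where its adjusted p was under 0.05.

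**Figure D1:**
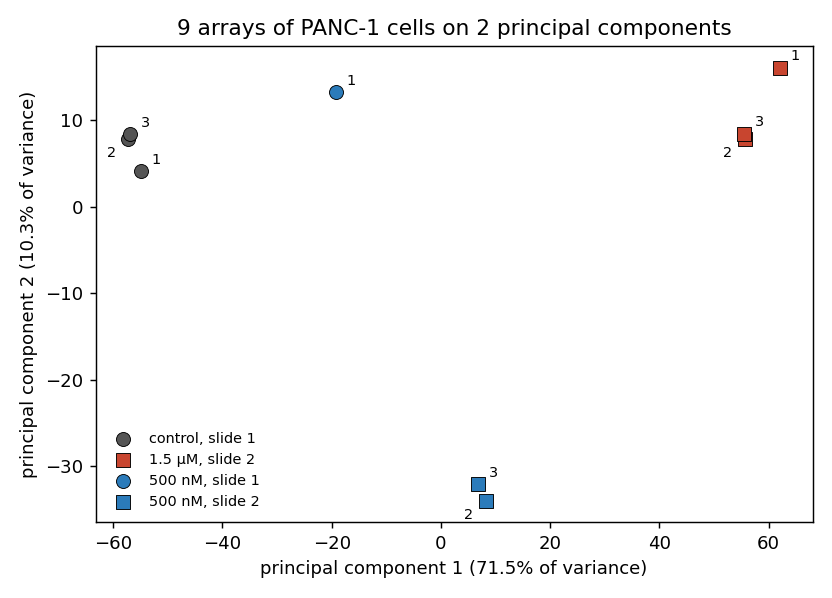
The 9 arrays on the first 2 principal components of the 20285 genes with a value on every array. Points are coloured by group, with circles for slide 1, squares for slide 2 and the replicate number beside each. Component 1 (71.5% of variance) runs from the controls at -57.2 to -54.9 to 1.5 µM at 55.5 to 62.1, and 500 nM replicate 1 (-19.2) lies apart from replicates 2 and 3 (8.28 and 6.73).

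At 500 nM against control, which asks what the lower dose did, 28 of 32 targets of the integrated stress response rose, and 41 of 42 genes of mitosis and 32 of 43 of DNA replication fell (12 of 43 with slide as a block). These lists passed camera at the preset correlation but not at adjusted p = 0.21, 0.21 and 0.45 with an estimated correlation. SESN2, a stress-induced regulator of mTORC1, rose by 1.93 ± 0.08, and DDIT3, which encodes the stress transcription factor CHOP, by 1.42 ± 0.06. Among genes with a current symbol and above background on all arrays compared, the largest rises were in TM4SF19, a tetraspan membrane protein (2.88 ± 0.09), the collagen receptor subunit ITGA2 (2.64 ± 0.59) and SPOCD1 (2.62 ± 0.09). Next came the lysosomal membrane protein LAMP3 (2.61 ± 0.12), the siderophore-binding lipocalin LCN2 (2.53 ± 0.13), the thrombin receptor thrombomodulin THBD (2.33 ± 0.12), the hexokinase-related HKDC1 (2.33 ± 0.08) and KLHDC7B (2.31 ± 0.13). TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell most (-2.11 ± 0.16), then the water and glycerol channel AQP3 (-1.87 ± 0.23), the natriuretic peptide precursor NPPC (-1.79 ± 0.21). CDH18 (-1.73 ± 0.25), the glucagon receptor GCGR (-1.70 ± 0.34), ATOH8 (-1.65 ± 0.20), E-cadherin CDH1 (-1.61 ± 0.08) and INAVA (-1.59 ± 0.10) followed. Some genes were above background in only 1 of the groups. LRRD1 was at least 4.47-fold, the protease inhibitor CSTA at least 4.32-fold and RNF113B at least 4.09-fold higher. The stem cell factor SOX2 was at least 2.22-fold, the lipid flippase ATP8A1 at least 2.20-fold and the acetyltransferase NAT2 at least 2.09-fold lower. With slide as a block the log2 fold change of ITGA2 was 0.96, that of LRRD1 1.48 and that of RNF113B 1.18, all still called. For LRRD1 and RNF113B these log2 values, which rest on replicate 1, lie below the bounds given above. GCGR was not called with slide as a block (adjusted p = 0.0675). NAT2 lost its call in 10 other settings, for example without control replicate 1 (adjusted p = 0.102).

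Of the 32 measured targets of the integrated stress response, 28 rose and 1 fell at 500 nM, and the counts adjusted over the list alone were equal. TRIB3, a pseudokinase induced by CHOP, rose by 1.68 ± 0.09 and the cystine and glutamate exchanger SLC7A11 by 1.36 ± 0.08. The list median was 0.90 (camera, adjusted p = 4.78e-17, and adjusted p = 0.21 with an estimated correlation) and 0.96 with slide as a block. In the mitosis list 41 of 42 members fell, also 41 adjusted over the list alone. The median was -0.66 (adjusted p = 5.12e-20, and adjusted p = 0.21 with an estimated correlation) and -0.54 with slide as a block. The mitotic kinesins KIF20A (-1.11 ± 0.08) and KIF11 (-0.66 ± 0.06) and the kinetochore gene NDC80 (-0.78 ± 0.08) were among them. Of 43 genes of DNA replication 32 fell, 35 adjusted over the list alone and 12 with slide as a block. Their median was -0.39 (adjusted p = 1.15e-10, and adjusted p = 0.45 with an estimated correlation) and -0.32 with slide as a block. Among them were thymidine kinase TK1 (-0.66 ± 0.07) and the ribonucleotide reductase subunit RRM2 (-0.76 ± 0.10).

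Immediate early genes, the fast response to growth signals, rose at 500 nM in 18 of 30 and fell in 1 (19 and 1 adjusted over the list alone). The list median was 0.40 (camera, adjusted p = 1.14e-06, and adjusted p = 0.21 with an estimated correlation) and 0.53 with slide as a block. ATF3 rose by 1.55 ± 0.12 and the phosphatase gene DUSP5 by 1.20 ± 0.08. Among NF-kB targets 13 of 21 rose and 1 fell (16 and 2 adjusted over the list alone). The members had a median of 0.58 (adjusted p = 5.21e-06, and adjusted p = 0.21 with an estimated correlation) and 0.62 with slide as a block. Examples were TRAF1 (1.73 ± 0.11), the mitochondrial superoxide dismutase SOD2 (1.09 ± 0.09) and the chemokine CXCL2 (0.90 ± 0.10). NRF2 targets of the oxidative stress response rose in 12 of 17 (13 adjusted over the list alone). As a set they had a median of 0.35 (adjusted p = 6.09e-06, and adjusted p = 0.068 with an estimated correlation) and 0.37 with slide as a block. Members that changed included heme oxygenase HMOX1 (0.90 ± 0.11) and malic enzyme ME1 (0.92 ± 0.09). Hypoxia genes outside glycolysis rose in 8 of 19 and fell in 3 (9 and 3 adjusted over the list alone, 8 and 0 with slide as a block). The median was 0.17 (adjusted p = 0.00454, and adjusted p = 0.45 with an estimated correlation) and 0.23 with slide as a block. Members that passed included NDRG1 (1.57 ± 0.12), DDIT4 (1.28 ± 0.08) and the angiogenic factor VEGFA (1.06 ± 0.08).

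Transcripts of the mitochondrial genome, a list set in advance as a sign of RNA quality, rose at 500 nM in 6 of 9 and fell in 2, COX2 and ND5 (equal counts adjusted over the list alone), both of which lost the call with slide as a block (adjusted p = 0.196 and 0.337). Their median was 0.48 (camera, adjusted p = 0.00527, and adjusted p = 0.45 with an estimated correlation) and 0.45 with slide as a block. The ATP synthase subunit ATP6 rose by 0.90 ± 0.07 and the complex I subunit ND2 by 0.80 ± 0.10. Ribosomal protein genes rose in 6 of 34 (2 adjusted over the list alone and 2 with slide as a block), with a median of 0.12 (adjusted p = 0.00162, and adjusted p = 0.407 with an estimated correlation) and 0.14 with slide as a block. The direction of this list turned under quantile scaling, where the median was -0.06 (adjusted p = 0.564).

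Of 23 glycolysis genes, 6 rose, 1 fell and 16 did not pass at 500 nM, with equal counts adjusted over the list alone. The list test was not passed (median 0.06, camera, adjusted p = 0.136), nor with slide as a block (0.09, adjusted p = 0.054). With quantile scaling 5 rose and 4 fell and the median turned to -0.0103, with the authors' log2 values 5 rose and 4 fell (median -0.00897), and with E1A spike-in centring 1 rose and 0 fell (median 0.15). Hexokinase HK2, which makes glucose 6-phosphate, rose by 1.19 ± 0.09 (adjusted p = 0.000158) and the glucose transporter SLC2A1 by 0.60 ± 0.08. Smaller rises were those of the pyruvate dehydrogenase kinase PDK1 (0.51 ± 0.07), ENO2 (0.42 ± 0.10), HK1 (0.35 ± 0.07) and pyruvate kinase PKM (0.26 ± 0.06). PGAM1, the phosphoglycerate mutase, fell by 0.32 (SE 0.08), and its call and that of PKM were lost with slide as a block (adjusted p = 0.184 and 0.0658). The lactate dehydrogenase LDHA stood at -0.13 ± 0.06 (adjusted p = 0.153). The HK2 probe lies on chromosome 2 from 75120331 to 75120390 (hg19).

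In total 6881 of 20298 genes were called at 500 nM by limma, 3147 higher and 3734 lower, and 644 of them changed at least 2-fold, 499 up and 145 down. With slide as a block 3700 were called, within slide 1 2973. Both set replicate 1 alone against the controls on its slide, and the count within slide 1 takes that lone array to vary like the 3 controls. With E1A spike-in centring 712 were called, of which 75.3% rose against 45.7% in the main setting. Without control replicate 2 the count was 4198, without control replicate 3 4199, without 500 nM replicate 2 4308 and without 500 nM replicate 3 4581.

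At 1.5 µM against control, which asks what the higher dose did, all 43 genes of DNA replication and 41 of 42 of mitosis fell. So did 21 of 24 histone genes and 24 of 42 of oxidative phosphorylation (16 with slide as a block). Stress response targets rose in 29 of 32. With an estimated correlation the histone list kept its call (adjusted p = 0.0486) and the others did not (adjusted p = 0.246, 0.246, 0.592 and 0.25). Of the genes with a current symbol and above background on all arrays compared, thrombomodulin THBD rose most (5.39 ± 0.12, 41.9-fold), then TM4SF19 by 4.85 ± 0.09, the cyclic nucleotide phosphodiesterase PDE2A by 4.69 ± 0.09, and LCN2 by 4.67 ± 0.13. FAM25A (4.44 ± 0.19), the small GTPase RAB39B (4.29 ± 0.11), LAMP3 (4.27 ± 0.12) and SPOCD1 (4.26 ± 0.09) came next. Among these genes the largest falls were in INAVA (-4.07 ± 0.10, 16.8-fold), the phospholipase PLCD4 (-3.73 ± 0.14), RASL11A (-3.71 ± 0.13) and the epithelial transcription factor GRHL3 (-3.69 ± 0.17). Falls of similar size were those of the receptor-modifying RAMP1 (-3.56 ± 0.15), FAM111B (-3.53 ± 0.20), RADIL (-3.52 ± 0.14) and the cell cycle transcription factor E2F2 (-3.50 ± 0.23). Of genes above background in only 1 of the groups, BEX4 was at least 14.1-fold, the interferon-induced RSAD2 at least 10.9-fold and cyclin D2, CCND2, at least 9.91-fold higher. TMSB15A was at least 15.9-fold, the prostaglandin synthase PTGS1 at least 15.7-fold and PPP1R1B at least 11.5-fold lower.

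All 43 measured genes of DNA replication fell at 1.5 µM, also 43 adjusted over the list alone. The list median was -1.68 (camera, adjusted p = 1.91e-19, and adjusted p = 0.246 with an estimated correlation) and -1.48 with slide as a block. RRM2 fell by 2.82 (SE 0.10), thymidylate synthase TYMS by 1.87 (SE 0.06) and DNA ligase LIG1 by 1.96 (SE 0.08). In the mitosis list 41 of 42 fell, 42 adjusted over the list alone. The members had a median of -1.42 (adjusted p = 2.9e-19, and adjusted p = 0.246 with an estimated correlation) and -1.29 with slide as a block. These included KIF20A (-2.37 ± 0.08) and KIF11 (-1.92 ± 0.06). Of 24 replication-dependent histone genes 21 fell, also 21 adjusted over the list alone, with a median of -0.73 and -0.67 with slide as a block. This list passed at the preset (adjusted p = 6.17e-08) and at adjusted p = 0.0486 with an estimated correlation. The histone H3 genes H3C2 (-2.13 ± 0.09) and H3C10 (-1.93 ± 0.08) were among them. At 500 nM 1 of the 24 histone genes had risen and 4 had fallen (adjusted p = 0.6, with 0 and 0 with slide as a block).

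Integrated stress response targets rose at 1.5 µM in 29 of 32 and fell in 2, with equal counts adjusted over the list alone. Together they had a median of 1.32 (camera, adjusted p = 2.38e-11, and adjusted p = 0.25 with an estimated correlation) and 1.37 with slide as a block. SESN2 rose by 2.98 ± 0.08, TRIB3 by 2.62 ± 0.09, DDIT3 by 2.49 ± 0.06 and SLC7A11 by 2.36 ± 0.08. Immediate early genes rose in 22 of 30 and fell in 2, equal adjusted over the list alone. As a set they had a median of 0.94 (adjusted p = 9.42e-07, and adjusted p = 0.246 with an estimated correlation) and 0.98 with slide as a block. Among them were ATF3 (3.29 ± 0.12), which is also in the stress response list, and DUSP5 (2.92 ± 0.08). NRF2 targets rose in 13 of 17 and fell in 2, equal adjusted over the list alone. The median was 0.70 (adjusted p = 3.18e-05, and adjusted p = 0.0486 with an estimated correlation) and 0.64 with slide as a block. Examples were HMOX1 (2.56 ± 0.11) and the sulfiredoxin SRXN1 (1.50 ± 0.09). Hypoxia genes rose in 14 of 19 and fell in 3, equal adjusted over the list alone. Their median was 0.46 (adjusted p = 0.00247, and adjusted p = 0.491 with an estimated correlation) and 0.74 with slide as a block. Members that changed included NDRG1 (3.39 ± 0.12) and VEGFA (1.89 ± 0.08).

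Nuclear genes of oxidative phosphorylation fell at 1.5 µM in 24 of 42, also 24 adjusted over the list alone and 16 with slide as a block. The list median was -0.22 (camera, adjusted p = 0.000324, and adjusted p = 0.592 with an estimated correlation) and -0.14 with slide as a block. Members that passed included the complex I subunits NDUFB3 (-1.09 ± 0.09) and NDUFA2 (-0.88 ± 0.06). Of 21 TCA cycle genes 14 fell, equal adjusted over the list alone, while 8 fell and 1 rose with slide as a block. The members had a median of -0.31 (adjusted p = 0.00114, and adjusted p = 0.246 with an estimated correlation) and -0.26 with slide as a block. These included the isocitrate dehydrogenase IDH2 (-1.07 ± 0.06) and fumarase FH (-0.95 ± 0.08). Mitochondrial transcripts fell in 5 of 9 and rose in 0, equal adjusted over the list alone. Their list test was not passed (median -0.39, adjusted p = 0.0655), but was with slide as a block (-0.30, adjusted p = 0.0481), and in the main setting they stood at adjusted p = 0.592 with an estimated correlation. Heat shock genes fell in 11 of 17, equal adjusted over the list alone, while 7 fell and 1 rose with slide as a block. As a set they had a median of -0.34 (adjusted p = 0.0101, and adjusted p = 0.592 with an estimated correlation) and -0.28 with slide as a block. Among them were the chaperones HSPA1B (-1.73 ± 0.12) and HSPA8 (-0.70 ± 0.08). The heat shock test was not passed with the mean of a gene's probes (adjusted p = 0.0575).

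Autophagy genes rose at 1.5 µM in 15 of 30 and fell in 1, equal adjusted over the list alone. The median was 0.21 (camera, adjusted p = 0.0203, and adjusted p = 0.592 with an estimated correlation) and 0.20 with slide as a block. With only these 2 groups in the fit the list was not called (adjusted p = 0.0514). The autophagosome gene MAP1LC3B rose by 1.56 ± 0.08, WIPI1 by 1.53 ± 0.08 and the kinase ULK1 by 1.81 ± 0.11. Apoptosis genes rose in 16 of 30 and fell in 6, equal adjusted over the list alone. Their median was 0.40 (adjusted p = 0.0137, and adjusted p = 0.357 with an estimated correlation) and 0.46 with slide as a block. They included both the pro-death PMAIP1 (1.46 ± 0.06) and HRK (2.32 ± 0.11) and the anti-death MCL1 (1.00 ± 0.06). NF-kB targets rose in 12 of 21 and fell in 4, equal adjusted over the list alone (7 and 2 with slide as a block). The list median was 0.61 (adjusted p = 0.0389, and adjusted p = 0.592 with an estimated correlation) and 0.44 with slide as a block. TRAF1 rose by 3.07 ± 0.11 while the monocyte-attracting chemokine CCL2 fell by 3.45 (SE 0.20). The NF-kB list was not called in 3 settings, with normexp, with only these 2 groups in the fit (adjusted p = 0.0597) and without 500 nM replicate 1 (adjusted p = 0.0612). Fatty acid synthesis fell in 10 of 17 and rose in 2 (10 and 3 adjusted over the list alone), for example FASN (-1.28 ± 0.08), with a median of -0.40 (adjusted p = 0.0445, and adjusted p = 0.592 with an estimated correlation). Nucleotide synthesis fell in 10 of 19 and rose in 1 (equal adjusted over the list alone, 6 and 2 with slide as a block), with a median of -0.34 (adjusted p = 0.0483, and adjusted p = 0.592 with an estimated correlation), for example the nucleoside transporter SLC29A1 (-0.83 ± 0.06). Neither was called with slide as a block (medians -0.30 and -0.22, adjusted p = 0.147 and 0.217), and over all alternatives the call was lost in 11 settings for fatty acid and 16 for nucleotide synthesis.

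In the glycolysis list at 1.5 µM, 6 of 23 members rose and 12 fell, equal adjusted over the list alone. The list test was not passed (median -0.18, mean 0.04, camera, adjusted p = 0.502), nor with slide as a block (-0.15, adjusted p = 0.854). HK2 rose by 2.73 ± 0.09 (adjusted p = 3.21e-07), SLC2A1 by 1.78 ± 0.08, PDK1 by 0.90 ± 0.07 and HK1 by 0.49 ± 0.07. ENO2 stood 0.39 ± 0.10 and the regulator PFKFB3 0.24 ± 0.08 higher. Falls were those of PGAM1 (-1.07 ± 0.08), LDHA (-0.90 ± 0.06), PGK1 (-0.64 ± 0.11), TPI1 (-0.52 ± 0.07) and ENO1 (-0.51 ± 0.07), with PFKM (-0.69 ± 0.07) and the lactate exporter SLC16A3 (-0.35 ± 0.07). Smaller falls were those of GAPDH (-0.27 ± 0.06), ALDOC (-0.25 ± 0.09), ALDOA (-0.23 ± 0.06), LDHB (-0.21 ± 0.07) and PKM (-0.18 ± 0.06). PFKL (0.38), PFKP (0.11), GPI (-0.04), PFKFB4 (-0.06) and SLC16A1 (-0.11) did not pass. With slide as a block 5 rose and 5 fell, LDHA, PGAM1, PFKM, TPI1 and ENO1. With E1A spike-in centring 5 rose and 3 fell, LDHA, PGAM1 and PGK1. A second kept probe changed in the same direction for HK2 (2.57), LDHA (-1.46), PGAM1 (-1.13) and TPI1 (-0.29), but that of SLC2A1 read -0.36 ± 0.24 (adjusted p = 0.22).

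**Figure D2:**
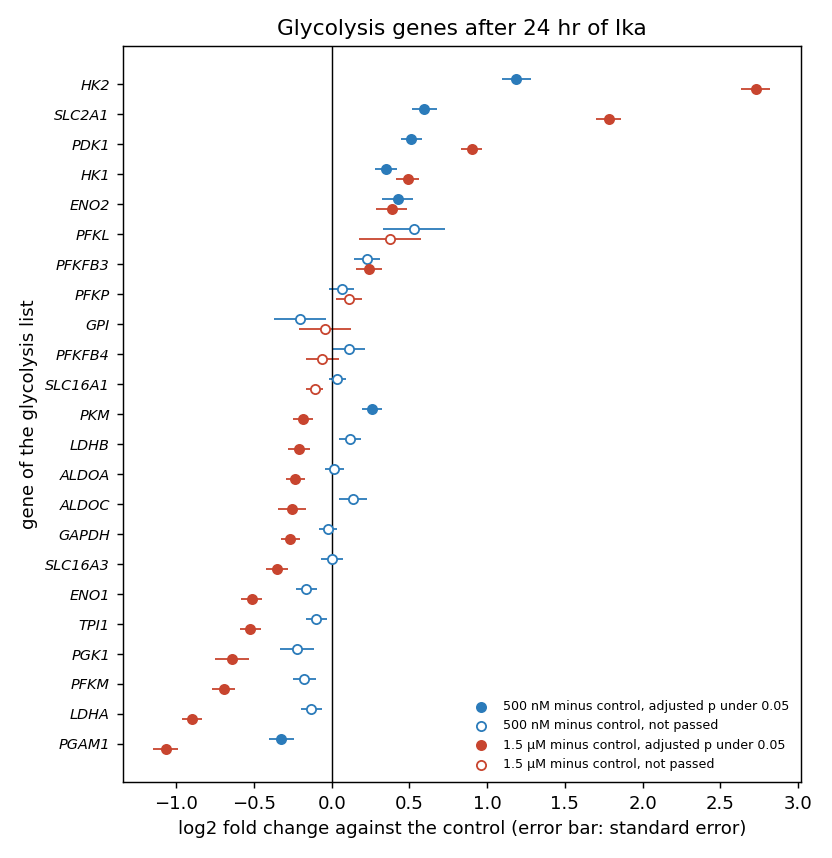
Log2 fold change against the control (horizontal axis, error bars are standard errors from limma, 3 arrays per group) of the 23 measured glycolysis genes at 500 nM (blue) and 1.5 µM (red), filled where the adjusted p was under 0.05. HK2 (1.19 and 2.73) and SLC2A1 (0.60 and 1.78) lie highest at both doses, PGAM1 (-1.07) and LDHA (-0.90) lie lowest at 1.5 µM, and SLC2A1 had a second probe at -0.36 at 1.5 µM.

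A further 18 lists were not called against the control at either dose in the main setting, with counts at 1.5 µM rising, falling and adjusted p from camera as follows. Clathrin-mediated endocytosis had 11 up and 9 down of 35 (adjusted p = 0.847, 11 and 8 adjusted over the list alone), with the arrestin ARRB1 at -2.05 ± 0.14 and the sorting nexin SNX9 at 0.89 ± 0.06. Lysosomal genes had 13 and 16 of 43 (0.969), with NEU1 at -1.23 ± 0.07. Cholesterol synthesis had 6 and 10 of 24 (0.482) and LXR targets 3 and 3 of 7 (0.969), with LPCAT3 at -1.07 ± 0.07 and ABCA1 at 1.03 ± 0.10. The unfolded protein response had 9 and 11 of 23 (0.877), with the chaperone HSPA5 at 1.50 ± 0.11 and WFS1 at -1.16 ± 0.07. Epithelial genes had 7 and 10 of 22 (0.29), with P-cadherin CDH3 at -2.57 ± 0.08, and mesenchymal and TGF-beta genes 6 and 15 of 26 (0.11), with SNAI2 at 2.12 ± 0.12. Interferon response genes had 13 and 5 of 25 (0.133, 13 and 6 adjusted over the list alone), with ISG20 at 2.28 ± 0.10, and p53 targets 9 and 6 of 22 (0.257), with GADD45A at 2.28 ± 0.09. Ribosomal proteins, called at 500 nM, had 11 and 1 of 34 (0.11, 9 and 1 adjusted over the list alone). The counts rising and falling moved with slide as a block to 12 and 4 for clathrin-mediated endocytosis, 9 and 3 for lysosomal genes, 6 and 5 for cholesterol synthesis, 1 and 2 for LXR targets, 8 and 7 for the unfolded protein response and 2 and 0 for ribosomal proteins.

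Of the remaining lists at 1.5 µM, amino acid metabolism had 10 genes up and 4 down of 16, with the aminotransferase GOT1 at 1.21 ± 0.11. Its camera test gave adjusted p = 0.0559, 0.0194 with slide as a block, and in the main setting 0.592 with an estimated correlation. MYC targets had 3 and 11 of 27 (0.146), mucins and glycan synthesis 5 and 2 of 11 (0.394), with the hexosamine enzyme GFPT1 at 1.61 ± 0.08. Iron genes had 6 and 3 of 14 (0.37), with the iron regulatory protein IREB2 at -0.89 ± 0.06, metallothioneins and zinc genes 3 and 3 of 10 (0.877) and the pentose phosphate pathway 1 and 2 of 7 (0.877). Markers of other cells were few above background: 4 and 1 of 5 acinar and endocrine genes (0.283), 3 and 1 of 6 immune and blood genes (0.877), with CD68 at 1.65 ± 0.11 and CD14 at -2.70 ± 0.15, and 1 and 0 of 3 stromal and endothelial genes (0.877). In these lists the counts adjusted over the list alone were equal. Of the lists of such markers, that of acinar and endocrine genes passed its test in 1 setting, at 500 nM with normexp, and the others in none. Blocked by slide, the counts rising and falling at 1.5 µM were 10 and 1 for amino acid metabolism, 1 and 5 for MYC targets, 1 and 2 for metallothioneins and zinc genes, 1 and 0 for acinar and endocrine genes and 1 and 1 for immune and blood genes. At 500 nM and with slide as a block, amino acid metabolism (median 0.20, adjusted p = 0.0144), lysosomal genes (0.11, 0.045), metallothioneins and zinc genes (0.34, 0.0488) and apoptosis (0.15, 0.0247) were called. In the main setting they stood at adjusted p = 0.652, 0.868, 0.45 and 0.45 with an estimated correlation.

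In total 12425 genes were called at 1.5 µM by limma, 6049 higher and 6376 lower, and 3016 of them changed at least 2-fold, 1596 up and 1420 down. With slide as a block 7774 were called, 3869 higher and 3905 lower, and no slide held both groups. With E1A spike-in centring, which raised the median of all genes by 0.18 log2, 7229 were called, of which 65.8% rose against 48.7% in the main setting.

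**Figure D3:**
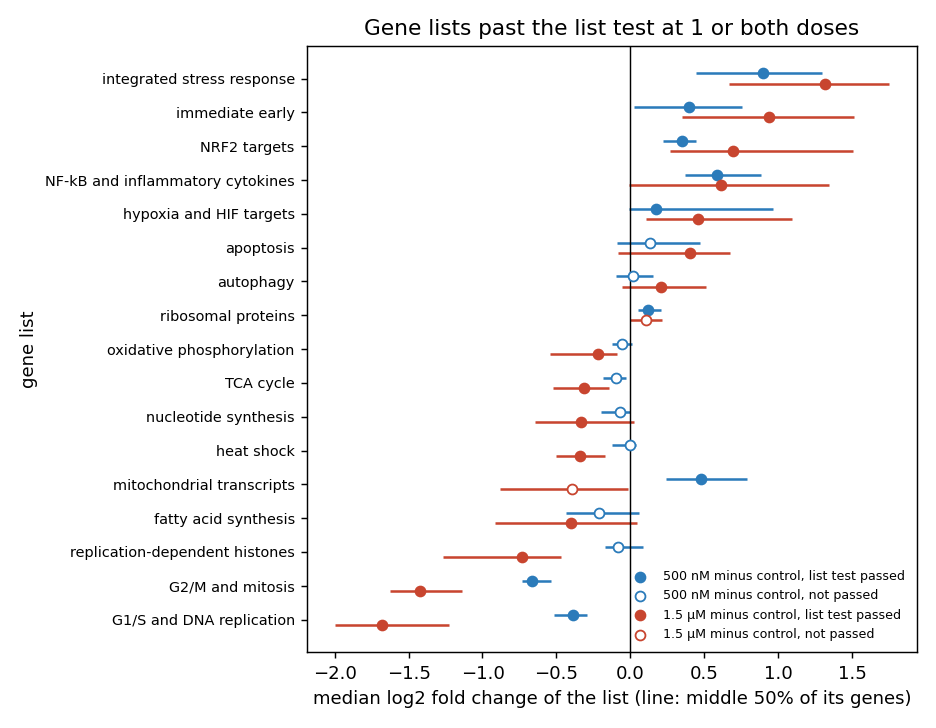
Median log2 fold change of each gene list that passed the camera test at 1 or both doses (horizontal axis, lines span the middle 50% of its genes), for 500 nM (blue) and 1.5 µM (red), filled where the test was passed at the preset correlation. DNA replication has the lowest median at 1.5 µM (-1.68) and the integrated stress response the highest (1.32), and the ribosomal median at 500 nM (0.12) flipped to -0.06 under quantile scaling.

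Between the doses, which asks whether 1.5 µM differed from 500 nM, 42 of 43 genes of DNA replication, 41 of 42 of mitosis and all 9 mitochondrial transcripts fell, and 19 of 32 stress response targets rose. None of these 4 lists kept its call with an estimated correlation (adjusted p = 0.183, 0.183, 0.197 and 0.395). All 9 mitochondrial transcripts, the list set as a sign of RNA quality, fell from 500 nM to 1.5 µM, equal adjusted over the list alone. The median was -1.08 (camera, adjusted p = 7.2e-07, and adjusted p = 0.197 with an estimated correlation) and -1.103 within slide 2 and with slide as a block. Among them were COX2 (-1.24 ± 0.10) and ATP6 (-1.08 ± 0.07). The V-ATPase subunit ATP6V0D2 rose by 3.53 ± 0.48, FAM25A 8.57-fold, THBD by 3.06 ± 0.12, TMIE by 2.65 ± 0.21 and PDE2A by 2.59 ± 0.09. FAM111B fell by 2.86 (SE 0.20), E2F2 by 2.81 (SE 0.23), CCL2 by 2.76 (SE 0.20), INAVA by 2.48 (SE 0.10) and ECEL1P2 by 2.34 (SE 0.07). TXNIP did not differ past the threshold (-0.19 ± 0.16, adjusted p = 0.411). CDH1 lay higher at 1.5 µM than at 500 nM by 0.71 ± 0.08, though below the control at both.

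**Figure D4:**
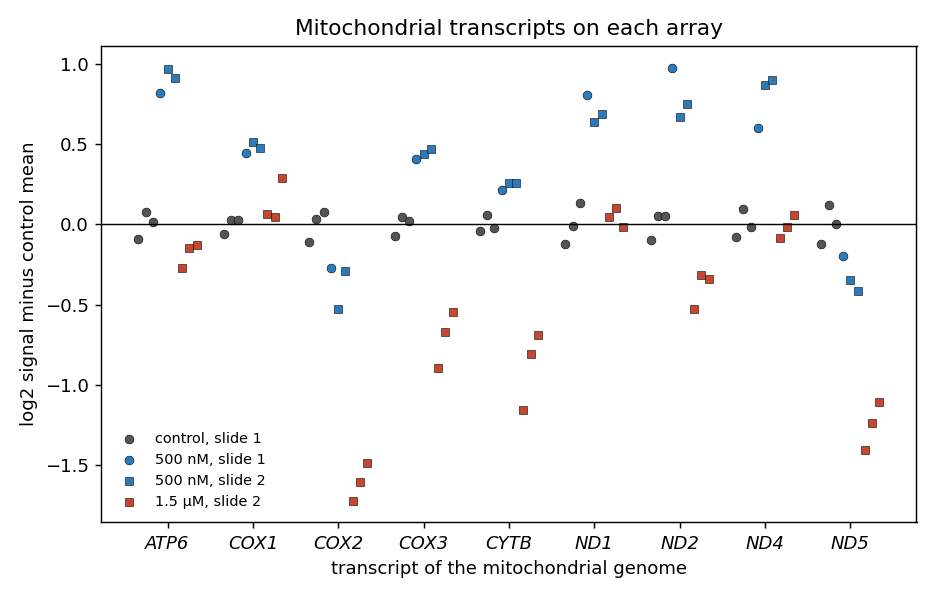
Log2 signal of 9 mitochondrial transcripts on each of the 9 arrays minus the mean of the 3 controls (vertical axis), coloured by group, with circles for slide 1 and squares for slide 2. For ATP6 the 500 nM arrays lie above the controls on both slides and the 1.5 µM arrays below them, and for COX2 (-1.60 at 1.5 µM) the 500 nM arrays also lie below.

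DNA replication genes fell from 500 nM to 1.5 µM in 42 of 43, 43 adjusted over the list alone, for example PCNA (-1.52 ± 0.08). Their median was -1.24 (camera, adjusted p = 3.23e-27, and adjusted p = 0.183 with an estimated correlation) and -1.19 with slide as a block. Mitotic genes fell in 41 of 42, also 41 adjusted over the list alone, for example PLK1 (-1.08 ± 0.07). As a set they had a median of -0.75 (adjusted p = 2.14e-20, and adjusted p = 0.183 with an estimated correlation) and -0.71 with slide as a block. Histone genes fell in 21 of 24, 22 adjusted over the list alone, for example H2AC11 (-1.81 ± 0.08). The histone median was -0.75 (adjusted p = 2.24e-12, and adjusted p = 0.0186 with an estimated correlation) and -0.81 with slide as a block. Immediate early genes rose in 20 of 30 and fell in 1 (21 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 3.85e-07, and adjusted p = 0.183 with an estimated correlation) and 0.49 with slide as a block. Stress response targets rose in 19 of 32 and fell in 2, equal adjusted over the list alone, with a median of 0.36 (adjusted p = 8.87e-06, and adjusted p = 0.395 with an estimated correlation) and 0.35 with slide as a block. NRF2 targets rose in 11 of 17 and fell in 1 (11 and 2 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.000137, and adjusted p = 0.0745 with an estimated correlation) and 0.46 with slide as a block. NF-kB targets split, 6 rising and 6 falling of 21 (adjusted p = 0.981).

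Oxidative phosphorylation genes fell between the doses in 20 of 42, 21 adjusted over the list alone. Their median was -0.21 (camera, adjusted p = 2.87e-05, and adjusted p = 0.468 with an estimated correlation) and -0.17 with slide as a block. TCA cycle genes fell in 10 of 21 (14, with 1 rising, adjusted over the list alone), with a median of -0.22 (adjusted p = 0.000655, and adjusted p = 0.197 with an estimated correlation) and -0.19 with slide as a block. Heat shock genes fell in 12 of 17, equal adjusted over the list alone, with a median of -0.29 (adjusted p = 0.000573, and adjusted p = 0.38 with an estimated correlation) and -0.30 with slide as a block. Autophagy genes rose in 15 of 30, equal adjusted over the list alone, with a median of 0.25 (adjusted p = 0.000772, and adjusted p = 0.38 with an estimated correlation) and 0.22 with slide as a block. Apoptosis genes rose in 15 and fell in 5 of 30, equal adjusted over the list alone, with a median of 0.28 (adjusted p = 0.00706, and adjusted p = 0.306 with an estimated correlation) and 0.26 with slide as a block. Hypoxia genes rose in 11 and fell in 4 of 19, equal adjusted over the list alone, with a median of 0.29 (adjusted p = 0.00965, and adjusted p = 0.461 with an estimated correlation) and 0.28 with slide as a block.

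Mesenchymal and TGF-beta genes fell between the doses in 14 of 26 and rose in 3 (15 and 3 adjusted over the list alone), for example THBS1 (-0.91 ± 0.09). Their median was -0.33 (camera, adjusted p = 0.00458, and adjusted p = 0.395 with an estimated correlation) and -0.25 with slide as a block. Nucleotide synthesis fell in 7 of 19, 8 adjusted over the list alone, with a median of -0.23 (adjusted p = 0.0148, and adjusted p = 0.497 with an estimated correlation) and -0.16 within slide 2. It was not called within slide 2 (adjusted p = 0.0648), with slide as a block (adjusted p = 0.0623) or without 500 nM replicate 1 (adjusted p = 0.064). In all its call was lost in 6 settings, the estimated correlation among them. Glycolysis genes fell in 12 of 23 and rose in 3 (13 and 3 adjusted over the list alone, but 1 and 2 with E1A spike-in centring), and the list test was not passed (median -0.24, adjusted p = 0.0534, and -0.27 within slide 2). The glycolysis test was passed with the mean of a gene's probes (adjusted p = 0.0227) and without 500 nM replicate 2 (adjusted p = 0.0331). In the main setting the list stood at adjusted p = 0.499 with an estimated correlation. P53 targets and amino acid metabolism were called with slide as a block (medians 0.20 and 0.21, adjusted p = 0.0442 for both), and in the main setting they stood at adjusted p = 0.519 and 0.619 with an estimated correlation. The 3 glycolysis genes that rose were HK2 (1.54 ± 0.09), SLC2A1 (1.19 ± 0.08) and PDK1 (0.39 ± 0.07), while PKM fell by 0.44 (SE 0.06). A total of 7440 genes were called between the doses by limma, 3486 higher and 3954 lower at 1.5 µM, 898 of them at least 2-fold. With slide as a block 8011 were called (4031 higher), within slide 2 6653 (3438 higher) and with E1A spike-in centring 2126 (1163 higher), so that 46.9% rose in the main setting against 50.3%, 51.7% and 54.7%.

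The changes at the doses were compared across genes, which are not independent replicates. THBD, TM4SF19, LCN2, LAMP3 and SPOCD1 stood among the 8 largest rises and INAVA among the 8 largest falls at both doses. Across 20298 genes the log2 fold changes correlated at r = 0.853 with a covariance of 0.309, beside 0.5004 and 0.0170 for simulated unchanged groups against the same controls (100 draws), a covariance difference of 0.292. Of the genes, 2802 rose at both doses, where independent lists would share 938, and 3315 fell at both, where they would share 1173. The simulated groups shared 0 at adjusted p under 0.05, a count that the adjustment makes likely where nothing changed, and they held no slide difference. The 3 controls were not divided, since that leaves fewer than 2 for 1 of the doses, so part of this overlap may come from them. Another part may come from the slides, since the controls lay on slide 1 and all treated arrays but 500 nM replicate 1 on slide 2. Among the 6117 genes called in the same direction at both doses, 86.7% had the larger change at 1.5 µM. The slope of the changes at 1.5 µM on those at 500 nM was 1.518. All 1.5 µM arrays but not all 500 nM arrays lay on slide 2. A slide difference alone could thus enlarge the change at 1.5 µM, and these values cannot tell it from the dose. A comparison with no array and no slide in common, chosen after the data were seen, set 500 nM replicate 1 minus the controls on slide 1 against 1.5 µM minus 500 nM replicates 2 and 3 on slide 2. There r was 0.460, 790 genes rose in both against 241 for independent lists, and 786 fell in both against 246.

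**Figure D5:**
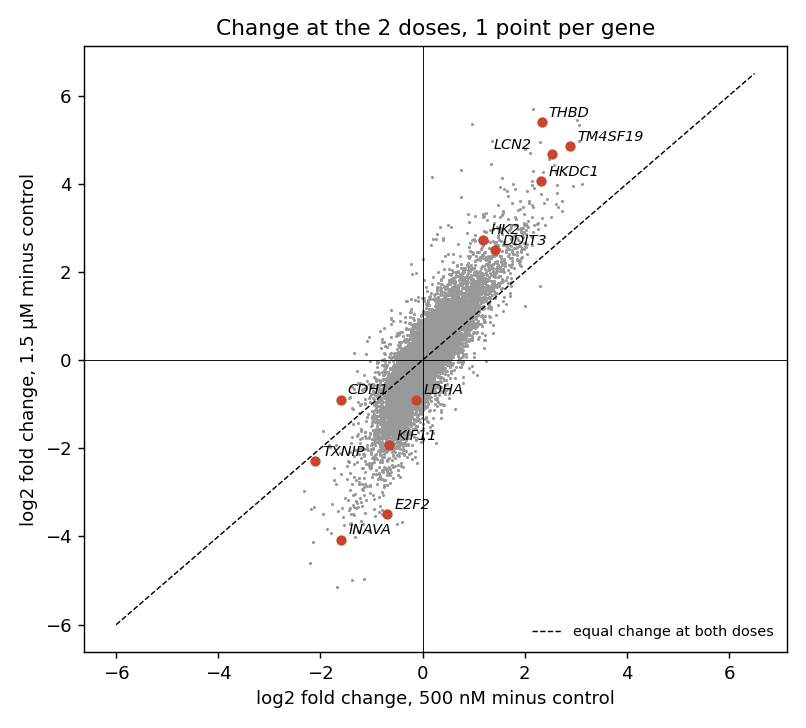
Log2 fold change at 500 nM (horizontal axis) and 1.5 µM (vertical axis) against the same 3 controls for 20298 genes, with named genes in red and a dashed line of equal change. THBD (2.33 and 5.39) and INAVA (-1.59 and -4.07) lie farther from 0 at 1.5 µM, and CDH1 (-1.61 and -0.90) lies nearer to 0.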

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

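All tests here are recorded as written before their values were computed, except the fits within each slide and some checks of 500 nM replicate 1. Those checks used genes chosen on 1 of the other 500 nM replicates, or at 1.5 µM against the controls. These exceptions were chosen after the data were seen. Values with slide as a block came from the run that gave the changes. They may have been at hand when the tests that use them were written. The mitochondrial list stood out because its change differed between the doses, by a median of -1.08 log2 from 500 nM to 1.5 µM. A count of 54 genes, the mitochondrial ND2 and COX3 among them, stood out because they were called in opposite directions at the doses and were also called between them. Among them, chosen after their values were seen, the MYC family gene MYCL was at -0.62 and then 0.92, the pro-death BMF at -0.75 and 0.42, the sterol transporter ABCG1 at -0.48 and 0.56, and the protease inhibitor SERPINA3 at 0.39 and -1.01. In data outside the comparisons, the spike-in probes, an E1A probe differed between the slides by up to 0.75 log2, and 6 of 8 such probes did not overlap between slides.

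Of 9 mitochondrial transcripts 6 rose and 2 fell at 500 nM, and 5 fell at 1.5 µM, where the list test was not passed (adjusted p = 0.0655). A difference between the slides could give such a shift, but with slide as a block their median at 500 nM was still 0.45. That value rests on 500 nM replicate 1 alone. Within slide 2 all 9 fell from 500 nM to 1.5 µM. No slide held both the controls and 1.5 µM, so the part below the controls stays open. Whether the amount of mitochondrial DNA or its transcription differed was not tested.

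HK2 and SLC2A1 rose while LDHA, PGAM1, TPI1 and ENO1 fell at 1.5 µM. A slide difference would be likely to cost some of these calls, and 6 of the 6 genes kept direction and call with slide as a block. These 6 were picked from the glycolysis list after its changes were seen. The falls picked all lie among those that kept their call with the block. PGK1, which fell more than TPI1 and ENO1 in the main setting, lost its call and was not picked. So 6 of 6 may follow from the choice of genes and cannot count against a slide difference. Over the whole list, 6 rising and 12 falling became 5 and 5 with slide as a block. No slide held both the controls and 1.5 µM, so a part played by the slides stays open. Loss of the brightest transcripts would lower other genes of like brightness, but the median change of 394 such genes was -0.0251. The choice of probe stays open for SLC2A1 and for ENO1, which had no second kept probe: 1 of 5 other kept probes of these genes went the opposite way, that of SLC2A1 at -0.36 and without a call.

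Replicate 1 of 500 nM stood apart from replicates 2 and 3 and lay on the other slide. Between probes of the same gene, its difference from them correlated at r = 0.0734 over 4542 genes, against 0.652 for the change at 1.5 µM. Replicate 2 minus replicate 3, on the same slide, gave 0.181 and also lay under the limit set for an effect of the slide on single probes, so the low value does not single out that effect. A weaker response of those cells might have lowered the genes that rose within slide 2, but their median difference was 0.12, against 0.07 for all genes. Genes at least 2-fold higher at 1.5 µM than in replicate 2 gave 0.15 against replicate 3, beside 0.08 for all genes. Those chosen on replicate 3 gave 0.09 against replicate 2, beside 0.06. Each of these choices favours genes that read low in the replicates on slide 2, which by itself can raise the difference. So these medians cannot count against a weaker response. The slope of its changes on those of replicates 2 and 3 was 0.452, which met the other part of that prediction. Genes that rose at least 2-fold at 1.5 µM against the controls rose less in replicate 1. Their median change was 0.49, against 1.02 and 0.95 in replicates 2 and 3. Genes that fell at least 2-fold stood at -0.49, -0.59 and -0.61. Replicates 2 and 3 share slide 2 with the 1.5 µM arrays, so a slide difference could add to this gap. Both explanations therefore stay open.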

How the results depend on the processing

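Signal over background limits what could be called: 52.3% to 56.0% of probes were well above background on an array. Across the alternatives, 13482 values of named genes kept direction and side of the threshold, 704 lost the call, 79 gained it and 12 reversed, and for the lists these numbers were 2475, 71, 64 and 2. In every setting, the estimated correlation aside, 8 of 9 lists kept their call at 500 nM, 10 of 15 at 1.5 µM and 14 of 15 between the doses. Of the calls of named genes, 61 of 154 were kept at 500 nM, 129 of 172 at 1.5 µM and 110 of 192 between the doses. With the estimated correlation no list kept its call at 500 nM. Only histones and NRF2 targets kept it at 1.5 µM, and only histones between the doses. The cause of the changes below was not tested, except that stricter thresholds leave fewer genes.

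Genes called at 500 nM were 6881 in the main setting, 712 with E1A spike-in centring, 4354 with no filter on dim probes, 3700 with slide or scan date as a block, 2973 within slide 1, 644 at 2-fold and 3002 at adjusted p under 0.01. At 1.5 µM 12425 became 7229 with E1A centring, 7774 with slide or scan date as a block and 3016 at 2-fold, and between the doses 7440 became 2126 with E1A centring, 898 at 2-fold and 4735 at adjusted p under 0.01. The E1A probes carry slide differences of their own. Leaving out 1 array gave 4198 to 9364 at 500 nM, the highest without 500 nM replicate 1, 10879 to 13569 at 1.5 µM and 5808 to 8014 between the doses. In these fits the glycolysis median ranged from 0.01 to 0.11 at 500 nM and from -0.18 to -0.15 at 1.5 µM. Over all settings it ran from -0.0103 (quantile scaling) to 0.15 (E1A centring) and from -0.18 to -0.00143 (E1A centring), and its test against the control was passed in none. Over genes called at either dose the doses correlated at r = 0.8795.

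The median of the list of ribosomal proteins at 500 nM turned to -0.0581 with quantile scaling and to -0.0574 with the authors' log2 values. With the mean of a gene's probes, HSPE1 at 1.5 µM turned to 0.0695, and between the doses ABCC3 to -0.0178, MELTF to 0.21 and MT1X to 0.0565. With slide or scan date as a block CD4 turned to -0.12 and CD79A to -0.0591 at 1.5 µM. Between the doses CEL was at -0.35 with slide or scan date as a block, within slide 2 and without 500 nM replicate 1, and reached 0.21 without 500 nM replicate 2. Replicate numbers did not pair: r between arrays of a number was -0.10 to 0.05, 3 of 18 correlated best with their own number, and a block on the number gave 5719, 11929 and 6580 calls.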

Other observations

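The gene sets below were written down with their predictions after the largest changes had been seen and before the sets were tested. Targets of TFE3 and TFEB, the transcription factors of lysosome and autophagy genes, were tested because ATP6V0D2, HKDC1 and LAMP3 were among the largest rises. Of 16 members at 1.5 µM, 10 rose, 3 fell and 3 did not pass, with a median of 0.39 (camera, p = 0.0198, p = 0.173 with an estimated correlation, and p = 0.00529 with slide as a block), and 9 of them also stand in a list fixed earlier. WIPI1, SQSTM1 and NEU1 had already been named as members of the autophagy and lysosome lists. The test of this set, not adjusted over lists, is thus in part a second test of the same values. WIPI1 (1.53 ± 0.08), SQSTM1 (1.17 ± 0.06), the GTPase RRAGC (1.05 ± 0.08) and FLCN (0.75 ± 0.12) rose, while NEU1 (-1.23 ± 0.07), PPARGC1A (-1.26 ± 0.25) and MCOLN1 (-0.38 ± 0.09) fell. Blocked by slide, 2 of the rises, ATP6V1H (-0.0324, adjusted p = 0.869) and GABARAPL1 (0.39, adjusted p = 0.0741), lost the call. So did 2 of the falls, PPARGC1A (-0.96, adjusted p = 0.145) and MCOLN1 (-0.25, adjusted p = 0.213). Wnt target genes were tested because AXIN2 and SOX2 were among the large falls. Of 6 measured members 0 rose and 5 fell, with a median of -0.58 (camera, p = 0.0185, p = 0.15 with an estimated correlation, and p = 0.0868 with slide as a block), such as RNF43 (-1.60 ± 0.11), DKK1 (-1.11 ± 0.13) and LEF1 (-0.79 ± 0.14). Blocked by slide, LEF1 (-0.63, adjusted p = 0.0895) and TCF7 (-0.0343, adjusted p = 0.828) lost the call, and 3 of the falls kept it.

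TXNIP fell at both doses, and lower activity of MondoA, a glucose-sensing transcription factor that drives TXNIP and ARRDC4, might have lowered both genes. ARRDC4 was at 0.15 ± 0.13 at 1.5 µM (adjusted p = 0.33), which does not bear out that hypothesis at the higher dose. At 500 nM ARRDC4 was at -0.43 ± 0.13 (adjusted p = 0.0356), and at -0.54 with slide as a block (adjusted p = 0.0835).

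Other splits of the 6 arrays of each comparison into 3 against 3 were tried. There are 10 splits, too few for a share under 0.05. The real split alone reached its own count of called genes, 1 of 10 in each comparison, and the highest count among the others was 2 for 500 nM against control and 0 for both other comparisons.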
